A study of Mus musculus with 6 samples.

How the data were processed

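The data are bulk RNA-seq of CD45-negative cells sorted from MB49 tumours, with 3 libraries from tumours of Y-KO cells and 3 from tumours of Y-Scr cells. Per the labels, libraries were made from poly-A RNA with a stranded kit. The deposited values are raw read counts per gene, 1 column per library. Per the file headers, the authors counted reads with featureCounts 1.5.3 and the Ensembl release 112 annotation of GRCm39, with no other option on the command line. By that version's defaults strand was not used, single reads and not read pairs were counted, and reads that fit several places or several genes were left out, so genes that overlap or resemble each other are uncertain. Among counts from 2 to 20, 81.4% in Y-KO and 81.0% in Y-Scr were even (mean of 3 libraries each), as paired reads counted singly would give. Per the submitters' processing notes, the tools were FastQC 0.12.1, MultiQC 1.13, Trimmomatic 0.39, STAR 2.5.2b and featureCounts 1.5.3, with the genome build GRCm39, also called mm39.

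The file held 57186 genes. Symbols came from a table of an older mouse annotation, matched by gene ID; 51880 IDs (90.7%) had one. Coordinates are those of the deposited file (GRCm39). Library totals ran from 42040955 to 52951031. Floors and intervals treat each count as independent and cover counting error only. Reads without molecular identifiers are not independent molecules, and both reads of a pair appear to be counted. Intervals may therefore be too narrow and floors too low. The floor for a gene with no counts was 3 counts over a group.

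Groups followed the sample titles. Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr on the group (a minimum count of 10 and a minimum total of 15) left 17837 genes, TMM gave the scaling, and the quasi-likelihood test compared Y-KO with Y-Scr with group alone in the model. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM values are counts scaled to the TMM-adjusted library size. Gene lists, 48 with 967 symbols of which 964 matched, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with Benjamini-Hochberg adjustment over the 47 lists with at least 5 tested genes. The list of lymphatic endothelial markers had 2 tested genes and was left out. Chromosomes were tested in the same way. Library-level measures were compared by exact two-sided permutation, where 3 against 3 allows no p under 0.1.

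The text names the Y-linked genes and their X-linked partners, the 12 genes with the largest fold in each direction, and up to 4 members with the smallest p of each list described. Genes of the large-fold group had an adjusted p under 0.05, no overlap between the groups and a mean of at least 2 CPM in the higher group, leaving out chromosome Y, unnamed gene models, pseudogenes and immunoglobulin and T cell receptor segments. Genes named outside this rule are said to have been chosen after their values were seen, and 1 gene that the rule names in a list is left out of the text and not reported here. Tests, lists and this rule were chosen before the data were examined.

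The alternatives were the replicate number as a block, DESeq2 1.42.0, limma-voom, other scalings and filters, a test against a fold of 1.5, other list tests, and leaving out each library. Added after seeing the data were sums of close library pairs, the pan-leukocyte mean as a covariate, halved counts, and for chromosomes the genes with a mean CPM of at least 4 in no cell type list. On simulated counts for the comparison of Y-KO with Y-Scr (17125 genes tested), with 50 genes changed at each fold, the edgeR step recovered 32.0% of genes changed 1.5-fold, 44.0% at 2-fold, 80.0% at 4-fold and 96.0% at 8-fold. In that simulation 10 of 141 calls fell on unchanged genes. The simulated libraries were independent, which the close pairs may not be, and far fewer genes were changed than were called in the data. These rates may therefore not hold for the data. Plots were drawn with matplotlib 3.10.9.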

Results

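Bulk RNA was sequenced from 6 mouse tumour samples. MB49, a mouse bladder carcinoma cell line of male origin, had been edited with CRISPR to lose its Y chromosome (Y-KO) or treated with a scrambled control (Y-Scr), and the cells were injected under the skin of C57BL/6J mice. Tumours were taken at 500 mm3 and CD45-negative cells, the fraction without the common leukocyte antigen, were sorted before RNA extraction. There were 3 Y-KO and 3 Y-Scr libraries, all with 1 batch label, and the total count per library ran from 42040955 to 52951031. The labels do not say whether the replicates came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. The design asks how CD45-negative cells of Y-KO tumours differ from those of Y-Scr tumours, and all differences are given as Y-KO minus Y-Scr.

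Transcripts of the Y-linked genes with broad expression were lower in Y-KO in all 5 members that could be tested, which checks the labels. The histone demethylase gene Kdm5d (chromosome Y, 897788 to 956786, GRCm39) stood at 3.33 ± 1.38 CPM (SD, n = 3) in Y-KO and 44.0 ± 4.04 CPM in Y-Scr, a 13.2-fold difference (log2 fold change -3.72, SE 0.30, edgeR adjusted p = 0.000171). Uty, related to the X-linked demethylase gene Kdm6a (chromosome Y, 1096861 to 1245759), was 10.1-fold lower, and the RNA helicase gene Ddx3y (chromosome Y, 1260771 to 1286629) was 9.04-fold lower, at 16.1 ± 6.98 against 146 ± 16.9 CPM. Eif2s3y, which encodes a translation initiation factor subunit (chromosome Y, 1010543 to 1028847), was 6.60-fold lower (log2 fold change -2.72, SE 0.32, edgeR adjusted p = 0.00112). Uba1y (chromosome Y, 818649 to 844224) had 0 counts in all Y-KO libraries and 42 over the Y-Scr libraries, at least 12.5-fold lower against a floor of 3 counts over the group. Its edgeR call (adjusted p = 0.0297) was lost without any single library other than Y-KO replicate 3, with adjusted p from 0.0699 to 0.145.

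**Figure D1:**
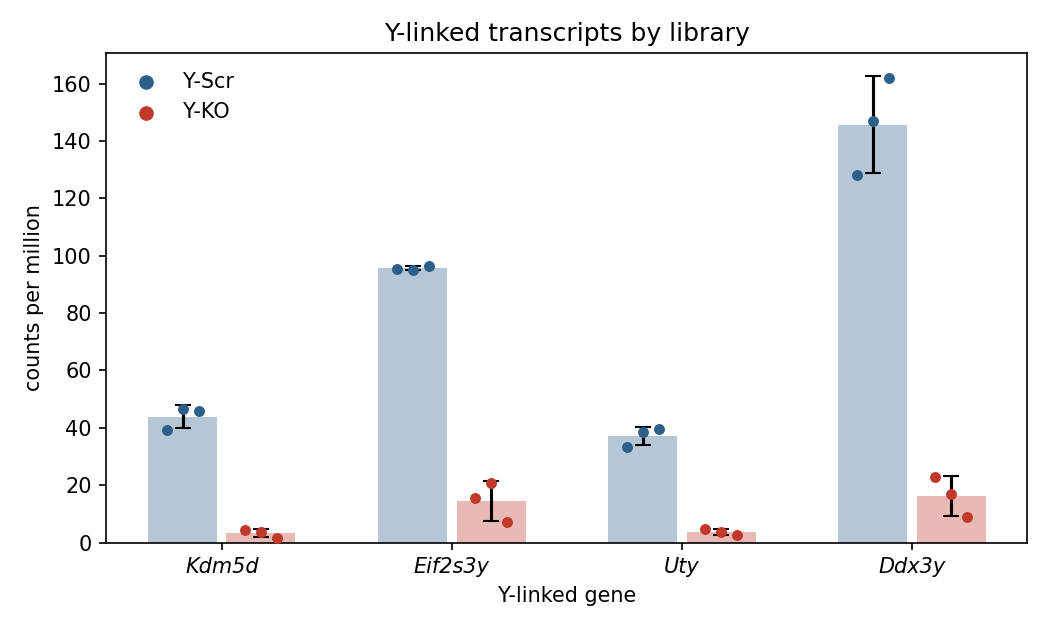
CPM, counts scaled to library size (vertical axis), of 4 Y-linked genes in each library; points are libraries, bars are means and error bars are SD (n = 3). Every Y-KO library lies below every Y-Scr library for all 4 genes, with Ddx3y at a mean of 16.1 CPM in Y-KO and 146 CPM in Y-Scr.

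The summed level of the genes between Uba1y and Usp9y (chromosome Y, 818649 to 1459782) was 37.6 ± 14.9 CPM (SD, n = 3) in Y-KO and 328 ± 23.8 CPM in Y-Scr, so that 11.5% of the Y-Scr level was left. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. Within Y-KO, replicates 1 and 2 stood at 47.3 and 45.1 CPM and replicate 3 at 20.5 CPM. The share left was 7.59% for Kdm5d, 9.92% for Uty, 11.1% for Ddx3y and 15.1% for Eif2s3y. Gm29650, a gene model in the same region (chromosome Y, 1048393 to 1049134) singled out after its values were seen, had 0 counts in Y-KO and 752 in Y-Scr, at least 224.5-fold lower against the same floor. Gm47283, at the far end of the chromosome (90796007 to 90827734) and also picked afterwards, differed by -0.18 (SE 0.15, edgeR adjusted p = 0.482). Whether its reads came from chromosome Y or from a similar sequence elsewhere was not tested. Its level therefore does not show whether that end of the chromosome was kept. None of the 7 X-linked partners of these genes passed the edgeR test, and 1 had an unadjusted p under 0.05. This partner was the deubiquitinase gene Usp9x, with a log2 fold change of -0.42 (SE 0.13, edgeR adjusted p = 0.0640). Without Y-KO replicate 3, 1 partner was higher and 3 were lower, and without Y-Scr replicate 1, 1 was lower.

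Of 17837 genes tested, 2871 differed between the groups, 1395 higher and 1476 lower in Y-KO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 259 were over 2-fold higher and 911 over 2-fold lower. In 2864 of the 2871 genes the 3 Y-KO values did not overlap the 3 Y-Scr values. Among all tested genes 37.7% were separated in this way. Chance gives 10% if all 6 libraries are independent, and more if libraries of a group share a tumour. With library size alone as the scaling, the median log2 fold change of all genes moved from -0.03 to -0.17 and the split became 730 higher and 2255 lower. The count depended on single libraries: it was 1733, 1801 and 6393 without Y-KO replicate 1, 2 and 3, and 1735, 1043 and 1037 without Y-Scr replicate 1, 2 and 3.

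The libraries of a group were not equally far apart. A chi-square statistic per gene, which averages about 1 for independent counts and about 2 where both reads of a pair are counted, was 12.9 between Y-KO replicates 1 and 2 at 1000 counts and more, against 161 and 160 between each of these and Y-KO replicate 3. Between Y-Scr replicates 2 and 3 it was 7.49, against 27.8 and 37.2 between each of these and Y-Scr replicate 1. From 20 to under 100 counts it was 10.0 and 5.89 in these close pairs, so that it was 1.29 and 1.27 times as high at high counts, against 15.9 and 15.6 times for the pairs with Y-KO replicate 3. Reads are not independent molecules, so a value above 1 or 2 that hardly grows with the counts can also come from libraries of 1 RNA or 1 tumour. The libraries were kept apart as labelled, nothing in the labels shows that the close pairs are separate tumours, and n = 3 may overstate the number of independent samples. Fits without Y-KO replicate 3 keep only the close pair in Y-KO, and fits without Y-Scr replicate 1 only the close pair in Y-Scr. Counts and p-values of these fits may rest on too small a spread. With each close pair summed into 1 sample, an alternative chosen after seeing the data, 496 genes passed, 136 higher and 360 lower, all of them among the 2871 and in the same direction.

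**Figure D2:**
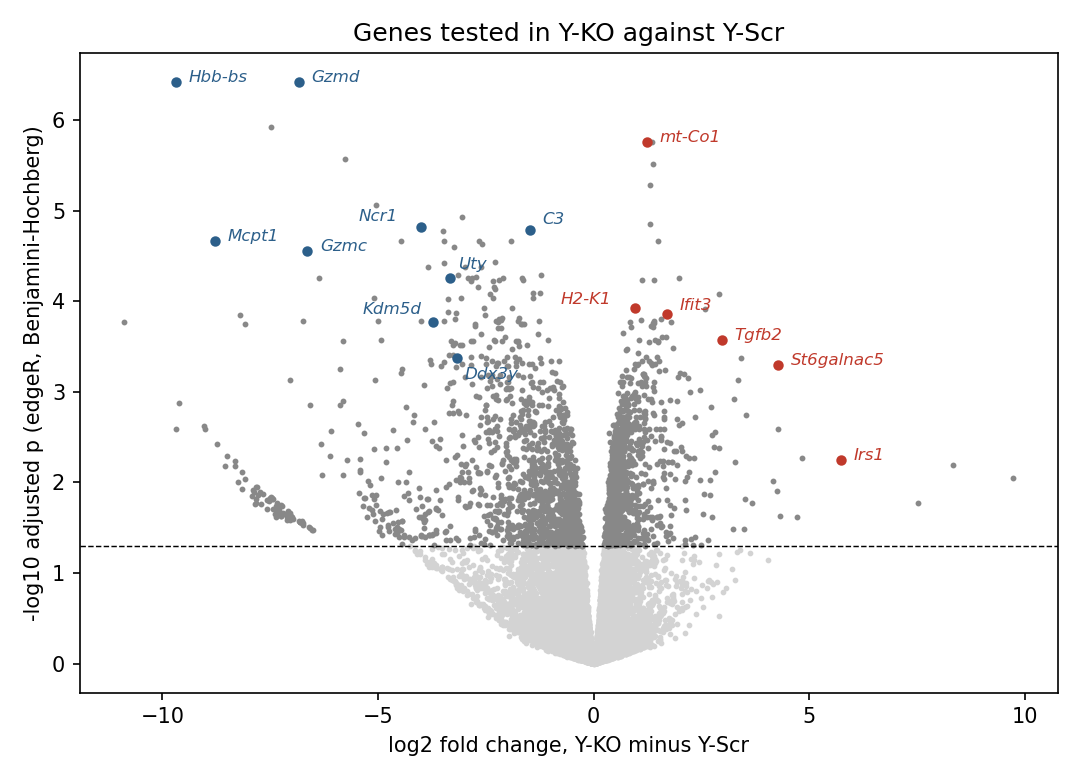
Log2 fold change (horizontal axis) against -log10 of the edgeR adjusted p (vertical axis) for each gene tested; dark grey points lie above the dashed line at an adjusted p of 0.05, and named genes are red where higher and blue where lower in Y-KO. Of the 2871 genes above the line, 1395 were higher and 1476 lower.

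The 12 genes with the largest fold higher in Y-KO included secreted factors and signalling genes. Il24, encoding a cytokine of the interleukin-10 family (chromosome 1, 130809811 to 130815191), had no counts in Y-Scr and was at least 112-fold higher, although Y-KO replicate 3 was at 0.36 CPM against 2.76 and 3.43 CPM in the others. Irs1, an adaptor of insulin receptor signalling, rose 53.2-fold to 2.20 ± 0.594 CPM (SD, n = 3), and Artn, encoding the neurotrophic factor artemin, rose 28.6-fold. The sialyltransferase gene St6galnac5 rose 19.3-fold (log2 fold change 4.27, SE 0.42, edgeR adjusted p = 0.000509). Tgfb2, encoding a transforming growth factor beta, rose 7.81-fold, from 3.11 ± 0.582 to 24.3 ± 7.46 CPM. The oxidase gene Duox1 and its maturation factor gene Duoxa1, neighbours on chromosome 2, rose 9.74-fold and 9.50-fold, and the interferon-induced Oas1g rose 10.2-fold. Cnfn, Lncenc1, Tppp and Brsk1 completed the group with log2 fold changes of 3.54, 3.42, 4.24 and 3.50. The edgeR call of Tppp was lost without Y-Scr replicate 1 or 2 (adjusted p = 0.0685 and 0.0695), and that of Brsk1 without Y-Scr replicate 2 or 3 (adjusted p = 0.0799 and 0.0613).

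The 12 genes with the largest fold lower in Y-KO included globin, mast cell protease and granzyme genes. Transcripts of the adult globin genes fell, with Hbb-bs at 0.162 ± 0.0970 CPM in Y-KO and 136 ± 10.5 CPM in Y-Scr (SD, n = 3), Hba-a1 179-fold lower, Hba-a2 293-fold lower and Hbb-bt 107-fold lower. The mast cell protease genes Mcpt1 and Mcpt2 fell 441-fold and 131-fold. Ms4a2, which encodes a chain of the high-affinity IgE receptor, had 2 counts over the Y-KO group, a ratio of 319 with a 95% counting interval from 87.9 to 2638. That interval treats each count as independent and may be too narrow. The granzyme genes Gzmc and Gzmd fell 99.7-fold and 115-fold, Gzmc from 248 ± 20.7 to 2.49 ± 1.42 CPM (edgeR adjusted p = 2.79e-05). Car8, encoding a carbonic anhydrase-related protein, and the glutamate receptor gene Grm6 had 0 counts in Y-KO, at least 99.7-fold and 92.2-fold lower. Ugt2b34, a glucuronosyltransferase gene, fell 95.7-fold. Multi-mapping reads were not counted, so the values of Hba-a1 and Hba-a2, which are near-identical, and of clustered granzyme and protease genes are uncertain.

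Of 47 gene lists fixed before the data were examined and tested, 24 passed camera with its preset correlation, 17 higher and 7 lower in Y-KO, and 9 passed fry. None of the 47 passed with an estimated correlation, where the smallest adjusted p was 0.205 and 5 had an unadjusted p under 0.05. The median and the camera direction differed in sign for NF-kappaB targets, and the mean and the camera direction for these, fatty acid synthesis and Yap/Taz targets, none of which passed. Counts of members below refer to edgeR calls adjusted over all genes tested. With the close pairs summed, 8 of the MHC class I genes, 6 of the type I interferon-stimulated genes and 4 of the stress response genes were higher, 16 of the T and NK cell markers were lower, and none of the glycolysis, Myc, DNA replication, mitosis, oxidative phosphorylation, hypoxia or MHC class II genes passed.

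Genes of MHC class I antigen presentation rose: 16 of 23 were higher, 1 was lower and 6 did not pass (17 and 1 adjusted over the list alone; camera adjusted p = 1.39e-09, adjusted p = 0.442 with an estimated correlation). The class I heavy chain gene H2-K1 rose 1.95-fold, from 1375 ± 26.9 to 2683 ± 213 CPM (SD, n = 3; edgeR adjusted p = 0.000119). Tap1, a subunit of the peptide transporter, rose 2.13-fold and B2m, the light chain, 1.61-fold (log2 fold change 0.69, SE 0.06). H2-Q4 rose 2.07-fold, while H2-Q7, named after its values were seen, was the 1 member that fell (log2 fold change -0.37, SE 0.10, edgeR adjusted p = 0.0405). The H2-Q7 call was lost without any single library other than Y-KO replicate 3 (adjusted p from 0.0670 to 0.138). H2 genes resemble each other closely, so reads that fit several of them were lost from the counts.

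Interferon-stimulated genes rose as well. Of 38 type I interferon-stimulated genes tested, 25 were higher and 1, Samd9l, was lower (28 and 1 adjusted over the list alone; camera adjusted p = 5.15e-12, adjusted p = 0.558 with an estimated correlation). The antiviral genes Ifit3, Ifit1 and Rsad2 rose 3.26-fold, 3.21-fold and 3.99-fold, Ifit3 from 11.7 ± 0.180 to 38.2 ± 5.08 CPM (SD, n = 3; edgeR adjusted p = 0.000137). Of 27 interferon-gamma-induced genes, 12 were higher and 1, Gbp8, was lower (13 and 2 adjusted over the list alone; camera adjusted p = 3.49e-05, adjusted p = 0.582 with an estimated correlation). Among them the chemokine gene Cxcl10 rose 3.80-fold and the guanylate-binding protein gene Gbp2 rose 3.09-fold. Samd9l and Gbp8 were named after their values were seen; the edgeR call of Samd9l was lost without Y-Scr replicate 2 or 3 (adjusted p = 0.0845 and 0.0637) and that of Gbp8 without Y-Scr replicate 1 or 3 (adjusted p = 0.0564 and 0.0733). Y-KO replicate 3 stood lower than the other Y-KO libraries: its mean over the type I list exceeded the Y-Scr mean by 0.49 on the log2 scale, against 0.97 for replicates 1 and 2. The mean log2 CPM of the interferon-gamma list was 5.08 and 5.10 in Y-KO replicates 1 and 2 and 4.32 in replicate 3, against 4.05, 4.06 and 4.15 in Y-Scr, and without Y-KO replicate 3 the counts of higher and lower genes in that list were 19 and 2.

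**Figure D3:**
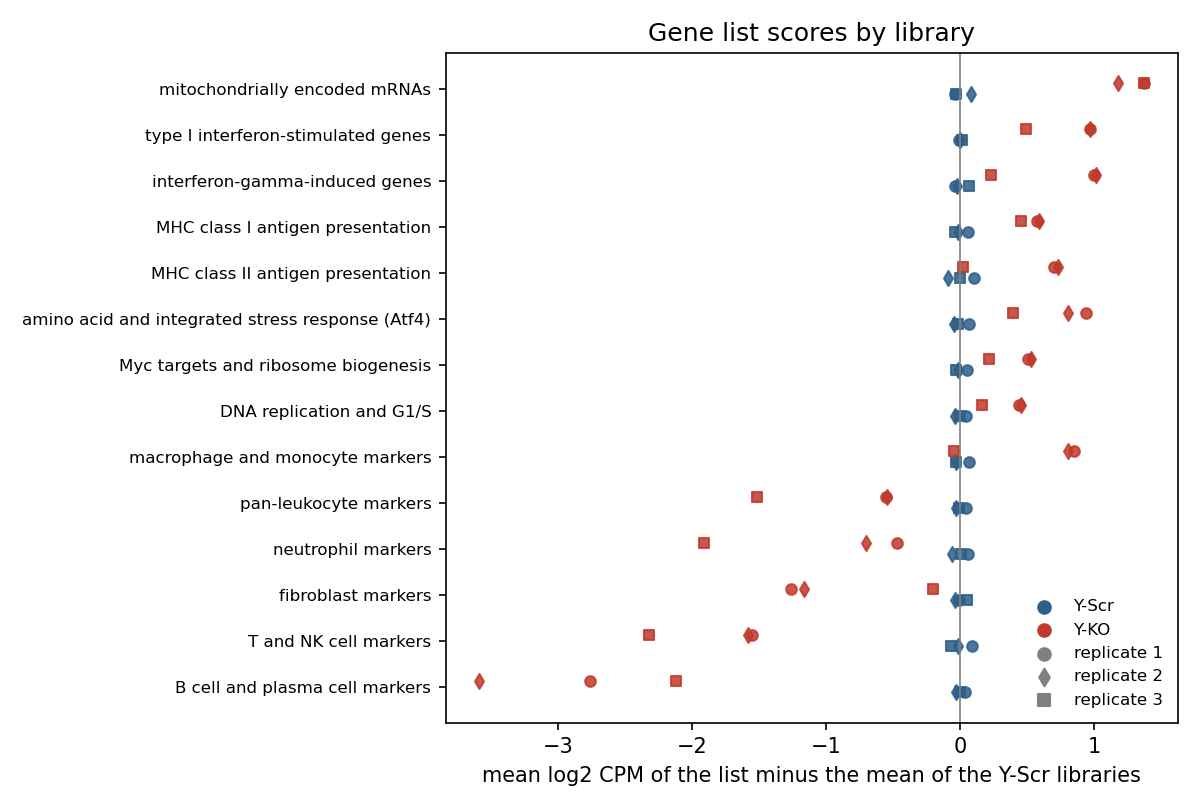
Mean log2 CPM of 14 gene lists in each library, relative to the mean of the Y-Scr libraries (horizontal axis); blue is Y-Scr, red is Y-KO, and the marker gives the replicate. The 3 Y-KO libraries lie to the right of Y-Scr for MHC class I and type I interferon genes and to the left for T and NK cell markers, while for macrophage markers Y-KO replicate 3 lies at the Y-Scr level.

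Markers of leukocytes, which the CD45-negative gate should remove, were well above the floor in both groups and moved in different directions. The mean log2 CPM of the pan-leukocyte list ran from 6.27 to 7.24 in Y-KO and from 7.76 to 7.83 in Y-Scr. Differences in any list may therefore come from leukocytes as well as from tumour cells, which was not tested. Of 23 T and NK cell markers, 20 fell, none rose and 3 did not pass (20 adjusted over the list alone; median log2 fold change -1.76, camera adjusted p = 3.43e-12, adjusted p = 0.558 with an estimated correlation). The natural cytotoxicity receptor gene Ncr1 fell 15.9-fold, from 57.8 ± 1.98 to 3.62 ± 0.976 CPM (SD, n = 3; edgeR adjusted p = 1.53e-05). The granzyme gene Gzma fell 8.85-fold, Foxp3, which marks regulatory T cells, 7.48-fold, and the T helper co-receptor gene Cd4 4.60-fold. The 3 members that did not pass, named after their values were seen, were Cd8a (log2 fold change 0.32, SE 0.19), Cd8b1 (-0.12, SE 0.20) and Ifng (0.01, SE 0.43). Without Y-KO replicate 3, which leaves only the close pair in Y-KO, Cd8a was higher (log2 fold change 0.53, edgeR adjusted p = 0.000644). The mean log2 CPM of the T and NK cell list was 4.02, 3.99 and 3.25 in Y-KO replicates 1, 2 and 3 and 5.66, 5.55 and 5.50 in the Y-Scr libraries. Of 12 B cell and plasma cell markers 8 fell (9 adjusted over the list alone; camera adjusted p = 4.59e-07, adjusted p = 0.439 with an estimated correlation), among them the immunoglobulin gene Ighm at 3.80-fold and Cd79a, a B cell receptor subunit, at 7.21-fold.

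Of 13 pan-leukocyte markers 7 fell (10 adjusted over the list alone; camera adjusted p = 0.00032, adjusted p = 0.582 with an estimated correlation). Ptprc, which encodes CD45 itself, fell 2.34-fold, from 567 ± 41.4 to 242 ± 93.1 CPM (SD, n = 3; edgeR adjusted p = 0.0157), a call lost without Y-Scr replicate 1, 2 or 3 (adjusted p from 0.0550 to 0.0746). The mean log2 CPM of the list was 7.23, 7.24 and 6.27 in Y-KO replicates 1, 2 and 3, against 7.83, 7.76 and 7.78 in Y-Scr. The count of 7 was 2 without any 1 of the Y-Scr libraries. Of 14 neutrophil markers 8 fell (8 adjusted over the list alone; camera adjusted p = 0.00274, adjusted p = 0.582 with an estimated correlation), including the receptor gene Csf3r at 2.73-fold. The neutrophil mean log2 CPM was 4.99 and 4.76 in Y-KO replicates 1 and 2 and 3.55 in replicate 3, against 5.52, 5.402 and 5.47 in Y-Scr, and the count of 8 was 2, 2 and 1 without Y-Scr replicate 1, 2 and 3. Of 20 macrophage and monocyte markers, 9 rose and none fell (12 and 1 adjusted over the list alone; camera adjusted p = 0.000931, adjusted p = 0.600 with an estimated correlation), with the complement genes C1qc and C1qb 2.27-fold and 2.09-fold higher and the apolipoprotein gene Apoe 1.93-fold higher. The macrophage mean of Y-KO replicates 1 and 2 exceeded the Y-Scr mean by 0.83 on the log2 scale, and that of Y-KO replicate 3 differed from it by -0.05; without Y-KO replicate 3, 16 macrophage markers were higher and 1 was lower. Of 10 MHC class II genes 7 rose (7 adjusted over the list alone; camera adjusted p = 0.0163, adjusted p = 0.600 with an estimated correlation), among them H2-DMb1 at 2.06-fold, a call lost without Y-Scr replicate 2 or 3 (edgeR adjusted p = 0.0676 and 0.0697). The calls of most other members were lost in the same way: the count of 7 was 1, 1 and 8 without Y-KO replicate 1, 2 and 3, and 2, 0 and 0 without Y-Scr replicate 1, 2 and 3. The class II mean log2 CPM was 7.56 and 7.59 in Y-KO replicates 1 and 2, and 6.88 in Y-KO replicate 3, within the Y-Scr range of 6.77 to 6.96. With the close pairs summed, the class II list no longer passed (adjusted p = 0.0850).

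Of 8 erythroid and platelet markers 5 fell (5 adjusted over the list alone; camera adjusted p = 0.000146, adjusted p = 0.305 with an estimated correlation), the globin genes above among them. Of 26 fibroblast markers 8 fell and none rose (10 adjusted over the list alone; camera adjusted p = 0.00138, adjusted p = 0.582 with an estimated correlation). The complement gene C3 fell 2.80-fold, from 507 ± 8.76 to 181 ± 6.01 CPM (SD, n = 3; edgeR adjusted p = 1.64e-05). The mean log2 CPM of the fibroblast list was 3.53 and 3.63 in Y-KO replicates 1 and 2, but 4.59 in Y-KO replicate 3, against 4.79, 4.76 and 4.84 in Y-Scr. Of these markers 17 were lower without Y-KO replicate 3, and 5 without Y-KO replicate 2 or any 1 of the Y-Scr libraries. The surface glycoprotein gene Thy1 fell 3.38-fold and the collagen genes Col5a1 and Col3a1 fell 2.84-fold and 4.71-fold.

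All 13 mitochondrially encoded mRNAs rose (13 adjusted over the list alone; median log2 fold change 1.31, camera adjusted p = 1.01e-13, adjusted p = 0.205 with an estimated correlation). The cytochrome c oxidase gene mt-Co1 rose 2.34-fold and the cytochrome b gene mt-Cytb 2.57-fold (edgeR adjusted p = 1.75e-06 for each). Mitochondrial genes took 6.41% ± 0.0278 (SD, n = 3) of the counts in Y-KO and 2.93% ± 0.0644 in Y-Scr (exact two-sided permutation p = 0.1). Genes with at least 1 count numbered 21092 ± 599.8 in Y-KO and 23600 ± 186.7 in Y-Scr (exact two-sided permutation p = 0.1). Reads of some mitochondrial genes also fit nuclear copies and were not counted.

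Of 25 genes of the amino acid and integrated stress response, driven by the transcription factor Atf4, 19 rose (22 adjusted over the list alone; camera adjusted p = 3.62e-11, adjusted p = 0.558 with an estimated correlation). The asparagine synthetase gene Asns rose 3.02-fold, from 60.1 ± 3.79 to 181 ± 32.2 CPM (SD, n = 3; edgeR adjusted p = 0.000246). The pseudokinase gene Trib3 rose by 1.32 on the log2 scale, the amino acid transporter gene Slc7a5 2.30-fold and Shmt2, of mitochondrial serine metabolism, 2.31-fold. Of 29 Myc targets and ribosome biogenesis genes, 17 rose (24 adjusted over the list alone; camera adjusted p = 1.39e-09, adjusted p = 0.581 with an estimated correlation), with the nucleolar gene Npm1 at 1.54-fold and Ncl at 1.59-fold. Of 30 DNA replication genes, 11 rose (18 adjusted over the list alone; camera adjusted p = 1.31e-07, adjusted p = 0.581 with an estimated correlation), including the replication licensing gene Cdt1 at 1.65-fold and the helicase subunit gene Mcm7 at 1.43-fold. Of 32 mitosis genes 7 rose (12 adjusted over the list alone; camera adjusted p = 0.000158, adjusted p = 0.600 with an estimated correlation), with Ube2c at 1.61-fold. The edgeR calls of Aurkb, Bub1 and Cdca8, also among the 7, were lost without any single library other than Y-KO replicate 3 (adjusted p from 0.0538 to 0.128). The mitosis mean log2 CPM was 6.59 and 6.60 in Y-KO replicates 1 and 2, but 6.27 in replicate 3, against 6.24, 6.26 and 6.26 in Y-Scr. Replicate 3 also stood nearer to Y-Scr than replicates 1 and 2 for the stress response list (6.15 against 6.69 and 6.56, with Y-Scr at 5.82, 5.71 and 5.74), the Myc list (7.29 against 7.58 and 7.60, with Y-Scr at 7.12, 7.06 and 7.04) and the DNA replication list (5.51 against 5.78 and 5.80, with Y-Scr at 5.39, 5.30 and 5.34). The pan-leukocyte mean of Y-KO replicate 3 was also lower, at 6.27 against 7.23 and 7.24 in replicates 1 and 2. Whether leukocyte RNA contributes to the differences in these lists was not tested. The mitosis count was 22 without Y-KO replicate 3 and 1 without any other library. Without Y-KO replicate 1, 2 and 3 the Myc count was 7, 8 and 25 and the DNA replication count 4, 4 and 22. Without Y-Scr replicate 1, 2 and 3 the Myc count was 13, 5 and 7 and the DNA replication count 8, 4 and 4.

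Of 19 glycolysis genes 12 rose and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 0.00024, adjusted p = 0.558 with an estimated correlation). Gapdh rose 1.48-fold and Pgk1 1.36-fold, and Aldoc was the 1 that fell (log2 fold change -0.64, SE 0.10). Of 35 nuclear oxidative phosphorylation genes 6 rose (16 adjusted over the list alone; camera adjusted p = 5.86e-06, adjusted p = 0.582 with an estimated correlation), and of 27 hypoxia-induced genes 10 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.0249, adjusted p = 0.442 with an estimated correlation). Without Y-KO replicate 1, 2 and 3 the counts of higher genes were 8, 7 and 15 for glycolysis, 2, 2 and 23 for oxidative phosphorylation and 7, 7 and 13 for hypoxia. Without Y-Scr replicate 1, 2 and 3 they were 11, 5 and 5, then 12, 0 and 0, and 7, 4 and 5. The lower genes without Y-KO replicate 3 numbered 2, 1 and 5. The hypoxia list lost its call without Y-KO replicate 3 (adjusted p = 0.0853). Cholesterol biosynthesis (2 of 22 rose), DNA damage repair (2 of 28), the unfolded protein response (2 of 20) and cytosolic ribosomal proteins (4 of 35) passed camera with few members past the threshold, with adjusted p = 0.723, 0.581, 0.635 and 0.808 with an estimated correlation. Adjusted over the list alone, these counts were 2, 2, 0 and 4. For cholesterol biosynthesis the mean log2 CPM was 6.93 and 6.92 in Y-KO replicates 1 and 2, but 6.22 in replicate 3, below the 6.44, 6.43 and 6.42 of Y-Scr. For the unfolded protein response it was 7.59, 7.58 and 7.39 in Y-KO and 7.39, 7.38 and 7.38 in Y-Scr. Without Y-KO replicate 3, 20 cholesterol, 8 repair, 14 unfolded protein and 7 ribosomal protein genes were higher, and 1 repair and 5 ribosomal protein genes were lower. Without any other library, 1 cholesterol gene was higher, and at most 1 unfolded protein gene. The ribosomal protein count was 8 without Y-Scr replicate 1 and 0 without Y-Scr replicate 2 or 3. The median of the ribosomal protein list, 0.08, turned to -0.06 with library size alone as the scaling. That list lost its call without Y-KO replicate 3 (adjusted p = 0.399) or without Y-Scr replicate 2 or 3 (adjusted p = 0.101 and 0.143). The cholesterol and unfolded protein lists lost theirs without Y-KO replicate 1 (adjusted p = 0.107 for both) or 2 (adjusted p = 0.0928 for both), and with the close pairs summed (adjusted p = 0.115 and 0.1196). With genes of at least 1 CPM in 3 libraries, the unfolded protein and ribosomal protein lists did not pass (adjusted p = 0.0654 and 0.0703).

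Expression by chromosome was compared for 22 chromosomes, the mitochondrial genome included, and 3 passed camera. Mitochondrial genes were higher (median log2 fold change 1.36, adjusted p = 2.68e-18, adjusted p = 0.0203 with an estimated correlation) and Y genes lower (median -2.72, adjusted p = 7.31e-05, adjusted p = 0.166 with an estimated correlation). The 614 tested genes of chromosome 19 had a median log2 fold change of 0.15, with 118 higher and 42 lower (adjusted p = 0.00490, adjusted p = 0.185 with an estimated correlation). It passed camera without each library in turn, with 67, 65 and 193 genes higher and 28, 30 and 85 lower without Y-KO replicate 1, 2 and 3, and 84, 47 and 47 higher and 22, 18 and 18 lower without Y-Scr replicate 1, 2 and 3. Among its 419 genes with a mean CPM of at least 4 and in no cell type list, an alternative chosen after seeing the data, the median was 0.21. Chromosome 15 had a median of -0.14 and did not pass (adjusted p = 0.148), but passed as lower under that alternative (adjusted p = 0.00776) and with genes of at least 1 CPM in 3 libraries (adjusted p = 0.0337). Over its other camera alternatives the adjusted p of chromosome 15 ran from 0.145 to 0.414. Chromosome 6 had a median of -0.10 and passed camera with an estimated correlation (adjusted p = 0.0273) but not with the preset one (adjusted p = 0.148). By fry, which tests a set by itself and not against other genes, 18 chromosomes passed.

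**Figure D4:**
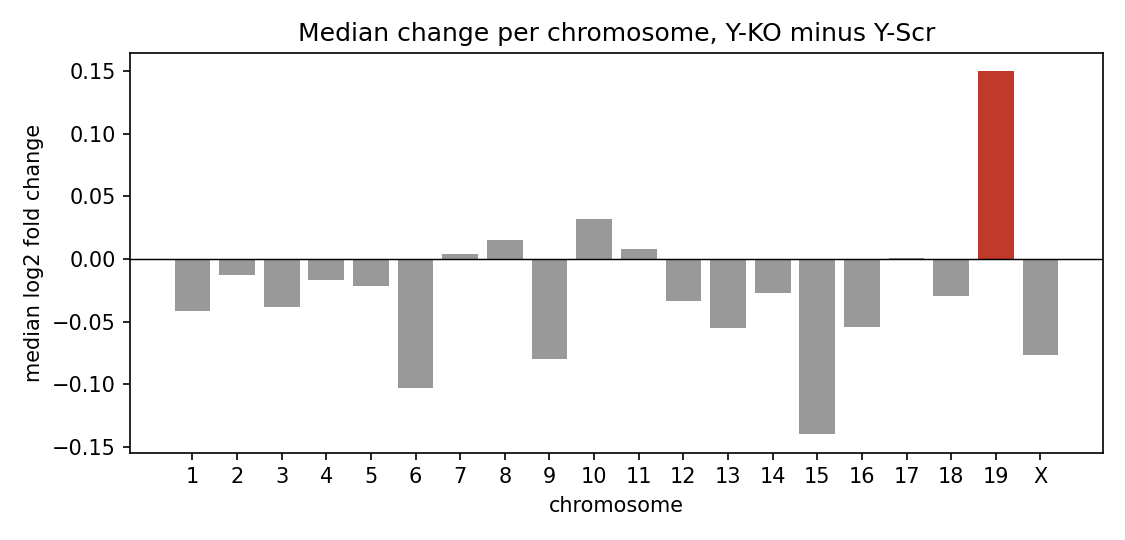
Median log2 fold change, Y-KO minus Y-Scr (vertical axis), of the tested genes of each chromosome (horizontal axis), without Y and the mitochondrial genome. Chromosome 19, in red because it passed camera with the preset correlation, has a median of 0.15, and chromosomes 6 and 15 have medians of -0.10 and -0.14.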

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

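The number of changed genes, 2871 as reported, stayed within 1.5 times for the replicate block, DESeq2, limma-voom, the other scalings and filters, and a fit without mitochondrial, ribosomal protein and Y-linked genes. Genes that passed both as reported and under an alternative had the same direction, which passing in 2 fits of the same libraries makes likely. Such genes numbered 1036 to 2862 on leaving out 1 library. With the pan-leukocyte covariate, chosen after seeing the data, they numbered 2034. With library size alone, 730 were higher and 2255 lower. Against a fold of 1.5 there were 666, 176 higher and 490 lower. Leaving out 1 library gave 1037 to 6393 genes, 461 to 3029 higher and 560 to 3364 lower. Among alternatives chosen after seeing the data, close pairs summed gave 496 genes, 136 higher and 360 lower, and Y-KO replicates 1 and 2 summed and all Y-Scr libraries summed (2 samples against 1) gave 100, 13 higher and 87 lower. The pan-leukocyte covariate gave 5170, 2745 higher and 2425 lower. The sums leave fewer samples and also remove the small spread within close pairs. Which of these lowered the counts was not tested, and for the other alternatives the cause was not tested either.

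The replicate number as a block gave 2066 genes, 946 higher and 1120 lower. Deviations of same-numbered libraries correlated at -0.00835, 0.00490 and -0.0145, which gave no sign that the numbers pair the libraries. A shared factor with a small effect is not excluded by these values. Of 179 named genes past the threshold, 120 to 178 kept their call on leaving out 1 library and 78 with close pairs summed. Of the lists, 24 passed as reported, 0 with an estimated correlation (5 at an unadjusted p under 0.05) and 9 by fry. With the pan-leukocyte covariate the ribosomal protein list turned lower (camera adjusted p = 0.610) and the pan-leukocyte list higher (camera adjusted p = 0.818), the covariate being built from that list. Besides these 2 of 47 lists, 8 came to pass, 2 no longer passed and 35 kept their call. By fry 18 chromosomes passed. Of these, 2, 4, 7, 10, 11 and 17 changed direction (fry adjusted p = 0.00195, 0.00539, 0.0315, 0.0367, 0.0367 and 0.0264). Chromosomes 5 and 8 also changed direction but did not pass (fry adjusted p = 0.0605 and 0.715). The fry test does not compare a chromosome with other genes, and the cause was not tested. Counts limit genes near the floor, such as Uba1y.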

Other observations

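Of 16 circadian clock genes, picked after their values were seen and with no test of the group, 10 were higher, 2 lower and 4 did not pass in Y-KO by edgeR; among all genes tested 16.1% passed. Without Y-Scr replicate 3, 6 were higher and 1 lower; the count of lower genes was also 1 without Y-KO replicate 1 or Y-Scr replicate 1 or 2. The output gene Dbp was 5.97-fold higher, from 11.6 ± 1.37 to 69.0 ± 17.5 CPM (SD, n = 3; edgeR adjusted p = 0.000123), Per2 was 4.71-fold higher, Tef 3.44-fold and Cry2 3.12-fold. Arntl, which encodes the activator Bmal1, was 3.50-fold lower (log2 fold change -1.81, SE 0.18, edgeR adjusted p = 0.000517). Harvest times are not given in the sources used here.

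Several lists that did not pass camera held genes with large changes. In the mesenchymal list 5 genes rose and 3 fell, with a median log2 fold change of 0.25. The collagen cross-linking gene Loxl2 fell 2.64-fold and the integrin gene Itgb3 4.48-fold, while Axl rose 1.33-fold (edgeR adjusted p = 0.00456). In the epithelial list 4 of 20 genes rose and 3 fell, with a median log2 fold change of -0.13: the keratin genes Krt14 and Krt19 rose 3.56-fold and 7.04-fold, and the adhesion gene Epcam fell 3.51-fold (edgeR adjusted p = 0.00586). Among 10 Wnt targets 1 rose and 5 fell, with Tcf7, Lef1 and Rnf43 9.41-fold, 8.32-fold and 4.96-fold lower; Tcf7 and Lef1 are also expressed by T cells. Among 27 checkpoint and suppressor genes 7 rose and 4 fell; Nos2 rose 2.63-fold and the ectonucleotidase gene Nt5e fell 6.96-fold. Without Y-KO replicate 3 the higher and lower genes numbered 9 and 5 in the mesenchymal list, 5 and 7 in the epithelial list, 3 and 6 in the Wnt list and 13 and 5 in the checkpoint list. Without Y-Scr replicate 2 or 3 they numbered 3 and 2, 3 and 1, 0 and 3, and 4 and 3. The mesenchymal numbers were also 3 and 2 without Y-KO replicate 1 or 2, and no Wnt target was higher without any 1 library other than Y-KO replicate 3.

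In the tests below, the splits of the libraries were set before their results were seen and the others were chosen afterwards. The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 2871 genes and the highest of the others 0; as many genes came from 1 of the 10. For lists the real split gave 24 and the highest other 23, from a split that put Y-KO replicates 1 and 2 with Y-Scr replicate 1; for chromosomes these were 3 and 2. Other splits that kept Y-KO replicates 1 and 2 together gave 21 lists each, so the list count follows a structure of the libraries as well as the groups.

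T and NK cell transcripts were lower in Y-KO. A lower share of all leukocytes in the Y-KO sort, as the only cause, would lower macrophage transcripts alike. The change of the macrophage mean exceeded that of the T and NK cell mean by 2.36 on the log2 scale. The within-group SD of this difference was up to 0.0724. Means of the other leukocyte lists fell, by -0.87 (pan-leukocyte), -1.03 (neutrophil), -2.83 (B and plasma cell) and -0.17 (dendritic cell), against -1.82 for T and NK cells. A lower share of leukocytes may therefore be part of the cause, which was not tested. Counts taken up by mitochondrial transcripts would lower every other transcript slightly (log2 change -0.0527), far short of the list median of -1.76. A change in which leukocytes pass the gate, and fewer T and NK cells in Y-KO tumours, both stay open and were not tested.

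Part of the Y-linked signal was left in Y-KO. If a share of MB49 cells had kept the chromosome and nothing else contributed, each gene of the region would keep a like share. The 4 genes at 0 in Y-KO would then have 86.4 counts, 79.3 of them from Gm29650. By these values Gm29650 kept less than the other genes. The 4 genes were picked for being at 0, and nearly all of the expected counts come from 1 gene model. The test therefore does not decide whether this was the whole cause. Male host cells in the sort may contribute: Y-linked level and pan-leukocyte level in replicate 3 were 0.443 and 0.513 times those of replicates 1 and 2, a quotient of 0.864. This rests on 1 library, the fibroblast mean moved the other way (2.02 times), and the sex of the hosts is not given in the sources used here. Xist, which female cells express, had 0, 0 and 21 counts in Y-KO replicates 1, 2 and 3. In Y-Scr it had 0, 0 and 16. With leukocyte transcripts present in every library, these counts argue against female hosts, although reads that fit Xist and an overlapping gene were not counted.

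MHC class I and interferon-stimulated transcripts were higher in Y-KO. The pan-leukocyte mean, which a higher share of all leukocytes would raise, was lower in Y-KO (difference -0.873 on the log2 scale, within-group SD of up to 0.556). Its exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. The values argue against more leukocytes of every kind. They do not address a change in which leukocytes were present. A higher share of macrophages cannot be told apart from a change in the tumour cells. In Y-KO replicate 3 the macrophage mean was at the Y-Scr level (-0.0504) while the MHC class I mean was higher by 0.45, but this is 1 library; in replicates 1 and 2 both were higher, by 0.83 and 0.58. A biological difference between Y-KO and Y-Scr tumour cells stays open, as a hypothesis.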
